A study of Homo sapiens with 4 samples.

How the data were processed

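RNA of 4 established human renal cell carcinoma cultures was measured, each on 1 one-colour array with Cy3-labelled cDNA. The cultures were the lines 786-O and ACHN and their sunitinib-resistant derivatives 7Su3rd and ACSu3rd. Per the labels' protocols, the derivatives came from the 3rd generation of xenografts in nude mice that received sunitinib orally at 40 mg/kg/day, 4 weeks on and 2 weeks off, and they were then cultured in 5 µM sunitinib. The parental group held 786-O and ACHN and the resistant group held 7Su3rd and ACSu3rd, so each group had n = 2 and each line had 1 array per state. The groups and the pairing of each derivative with its own line come from the labels and the design text.

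The deposited table held 71573 rows of probe intensity on a linear scale. The arrays were read with Agilent Feature Extraction 10.10, per the submitters' processing notes. What the authors did after that step is not given in the sources used here. The values were not scaled to a common level: the column medians were 117 in 786-O, 56.5 in 7Su3rd, 92.3 in ACHN and 107 in ACSu3rd. The values held no flags for detection or saturation and no dates or slides, so no batch could be examined.

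The 76 control rows were left out of every comparison of probes, which left 71497 probes. Each array was divided by its own 75th percentile over these probes and taken to log2. A probe was kept when its mean over the 4 arrays was at or above the median of all probes, which left 35749. The floor was 2 times the intensity of the negative control probe. It was 11.1 in 786-O, 44.1 in 7Su3rd, 11.0 in ACHN and 10.7 in ACSu3rd before scaling. In each comparison of a pair of arrays, both values were raised to the higher of the 2 scaled floors. Where only 1 side of a pair was at that floor, the difference is a bound and the fold is written as "at least". The scaling and the floor were chosen after the table was seen to be unscaled, while the filter, the thresholds, the tests within and over both pairs and the alternatives not named below as added were fixed before the data were examined. The number of arrays limits the precision of every value.

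Of the 71497 probes, 32205 had an identifier starting with CB, with no gene or catalogue in it. The other 39292 had an identifier that named a catalogue of transcripts or loci. No table paired probes with genes, so the unit of every count is the probe, and the rule of 1 probe per gene with its alternative, the median over the probes of a gene, had nothing to act on. For the same reason 0 of the 23 planned gene lists, with 431 genes in all, could be tested, and AXL, MET, LNCARSR, VEGFA, EPAS1, HIF1A and VHL are not analysed here. The planned rule for named genes (the 10 highest and lowest per pair, the 12 highest and lowest over both pairs, and 5 and 5 non-coding ones) is therefore given as counts per catalogue and as 2 identifiers in each direction. Names came from the identifiers themselves for 236 probes of HOX loci, of which 62 were kept. They came from the synonyms in the NCBI RefSeq gene table of assembly GRCh38.p14 for 5 XLOC identifiers with 1 symbol each, of which 3 were kept, while 1 more matched several symbols and stayed unnamed. The build of the array's design is not given in the sources used here, so no coordinates are printed. The HOX probes were picked as examples after their identifiers and values were seen. In place of the gene lists, probes were grouped into 22 classes by the catalogue in their identifier, a choice also made after the table was seen.

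Within a pair of arrays there is no replicate, so differences are given as log2 values with a 2-fold threshold and without a p-value. Per class, the median difference was placed among the medians of 10000 random lists of equal size, matched on mean expression in 20 bins. Over both pairs, limma was fitted with the cell line as a block and moderated by eBayes, two-sided, with Benjamini-Hochberg adjustment over the 35749 probes. The labels do not say that the 4 cultures were repeated, so the spread behind these p-values is that between the 2 lines. eBayes estimated an infinite prior degree of freedom, so that every probe was tested with 1 common standard error of 0.43 on the log2 scale. Classes were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The pairing rests on the shared cell line. As a check, the deviations from the group means of the arrays of 1 line correlated at r = 0.005 across probes. Line-specific expression kept by each derivative would make this value positive, so the check did not bear out the pairing. The limma step was tested on simulated data with 200 of 35749 probes changed. For the comparison over both pairs it called 7 of 35549 unchanged probes and 7 of 50 probes changed by 1 on the log2 scale. It called all 50 probes at each of the changes of 2, 3 and 4. The simulated noise had the same spread for every probe and array, which is what the fit assumes. Each simulated change was also equal in both lines. These counts therefore do not show how the fit performs where arrays or lines differ, as 7Su3rd does here.

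Alternatives were no filter, a filter at the 75th percentile, a filter on the highest array, quantile normalization, median centring, log2(intensity + 16), thresholds of 1.5-fold and 4-fold, no replicate block, eBayes with a trend or robust, and leaving out each array. No scaling, no floor, a floor at 3 times the negative control, and no filter together with no floor were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used.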

Results

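Expression was profiled on 4 one-colour arrays. They carry probes from catalogues that include non-coding RNAs, and 32205 CB probes whose targets are not given in the sources used here. 786-O and ACHN are established human renal cell carcinoma lines. 7Su3rd and ACSu3rd were derived from them in mice under sunitinib, an inhibitor of VEGF and PDGF receptor kinases, and each culture was measured on 1 array. The design compares each resistant derivative with its own parental line, to screen for long non-coding RNAs needed for resistance. After control rows were left out, 71497 probes remained, and 77.9% of them were above the floor of 2 times the negative control in 786-O, 53.0% in 7Su3rd, 74.8% in ACHN and 80.9% in ACSu3rd. The negative control probe read 22.0 on the 7Su3rd array and between 5.33 and 5.54 on the other 3 arrays. All differences below are resistant minus parental on the log2 scale after each array was scaled to its 75th percentile, over the 35749 probes kept by the filter. There is no replicate within a line, so no value within a pair has an error.

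In the 786-O pair, the most strongly lowered HOX-locus probe with signal on both arrays was hox-HOXC13-51, from the locus of a HOXC homeobox gene, which read 1383 in 786-O and 126 in 7Su3rd, a 5.43-fold decrease after scaling. The probe nc-HOXB9-193 was 3.08-fold lower in 7Su3rd. Probe nc-HOXC6-250 was at least 4.41-fold higher in 7Su3rd, and int-HOXC12-32 was 2.92-fold higher. Of the 62 HOX-locus probes kept, 5 were at least 2-fold higher and 9 at least 2-fold lower in 7Su3rd, and their median difference of -0.19 lay at percentile 0.50 of matched random lists. As a class over both lines they did not pass camera, with an adjusted p of 0.64. With quantile normalization the counts were 3 higher and 14 lower, and 2 of the probes above 2-fold, hox-HOXC11-57 and nc-HOXC8-144, had differences of 0.79 and 0.67. Over all probes, 5600 were at least 2-fold higher and 4732 at least 2-fold lower in 7Su3rd. Among those lower, 868 are bounds because the 7Su3rd signal was at the floor. The split between directions depended on the scaling: 54.2% of the changed probes were higher with the main scaling and 42.5% with quantile normalization, which gave 3739 higher and 5059 lower. With the intensities as deposited the median difference was -0.81 in place of 0.20, and 313 probes were higher and 15471 lower.

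The lists in this paragraph hold only probes with signal above the floor on all 4 arrays, so they may miss larger changes. The 10 such probes that rose most in 7Su3rd were 10.9-fold to 16.7-fold higher and held 7 CB, 2 UCSC and 1 XLOC identifiers. The 10 that fell most were 16.6-fold to 64.1-fold lower and held 6 CB, 2 XLOC, 1 RefSeq and 1 ENCODE identifiers. Among probes with a catalogue name, the 5 highest were 9.06-fold to 16.7-fold higher and the 5 lowest were 13.8-fold to 64.1-fold lower.

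In the ACHN pair, int-HOXB3-83, a probe of the HOXB3 locus, read 152 in ACHN and 1619 in ACSu3rd and was 9.50-fold higher after scaling. Other kept probes of that locus changed less than 2-fold, from -0.19 for int-HOXB3-70 to 0.62 for int-HOXB3-88. The probe nc-HOXD3-38 of the HOXD3 locus was 7.72-fold lower in ACSu3rd, and nc-HOXC6-244 was 2.54-fold lower. Of the 62 HOX-locus probes, 3 were at least 2-fold higher and 4 at least 2-fold lower, with a median of -0.03 at percentile 51.5 of matched random lists. Over all probes, 2222 were at least 2-fold higher and 2623 at least 2-fold lower in ACSu3rd. The median difference was 0.02, and with the intensities as deposited it was 0.18. The share of changed probes that were higher was 45.9% with the main scaling, 45.7% with quantile normalization and 64.0% with the intensities as deposited, which gave 3252 higher and 1826 lower.

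These lists too hold only probes with signal above the floor on all 4 arrays, those of the other pair included. The 10 such probes that rose most in ACSu3rd were 18.7-fold to 34.0-fold higher and held 9 CB and 1 H-InvDB identifiers. The 10 that fell most were 9.49-fold to 15.2-fold lower and held 7 CB, 1 RNAz, 1 UCSC and 1 ENST identifiers. Among probes with a catalogue name, the 5 highest were 15.9-fold to 19.4-fold higher and held 3 H-InvDB, 1 UCSC and 1 ENST identifiers. The 5 lowest were 8.79-fold to 10.6-fold lower.

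The screen asks for transcripts that changed in both lines. Probes nc-HOXD3-38 and nc-HOXD3-39, both from the HOXD3 locus, were the HOX-locus probes at least 2-fold changed the same way in both lines. They are a smaller share of the 62 HOX-locus probes kept than the 2210 probes so changed are of all 35749. nc-HOXD3-38 read 248 in 786-O, 37.7 in 7Su3rd, 225 in ACHN and 32.7 in ACSu3rd, which is at least 2.79-fold lower in 7Su3rd and 7.72-fold lower in ACSu3rd. nc-HOXD3-39 was at least 3.01-fold lower in 7Su3rd and 2.27-fold lower in ACSu3rd. Other kept probes of the HOXD3 locus did not fall 2-fold in both lines. int-HOXD3-3 had differences of -1.30 in the 786-O pair and -0.10 in the ACHN pair, and hox-HOXD3-49 had -0.28 and 0.15. Over all probes, 927 were at least 2-fold higher in both lines, where independent lists of these sizes would share 348. In the other direction 1283 were at least 2-fold lower in both lines, where independent lists would share 347. A further 56 were at least 2-fold higher in 7Su3rd and lower in ACSu3rd, and 51 the reverse. With the main scaling, 95.4% of the 2317 probes changed in both lines thus changed the same way. With the intensities as deposited the share was 75.8% of 2227 probes, and 538 were lower in 7Su3rd and higher in ACSu3rd. Without scaling, 147 were higher in both lines, where independent lists would share 28, and 1540 were lower, where they would share 790. With the main scaling, the probes changed the same way held 1165 CB identifiers and 1045 with a catalogue name.

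Among probes with signal above the floor on all 4 arrays, CB_000668 and CB_014387 had the largest rise in both lines. CB_000668 was 11.8-fold higher in 7Su3rd and 14.3-fold higher in ACSu3rd, and CB_014387 had log2 differences of 3.50 and 4.32. CB_008904 and CB_007732 had the largest fall: CB_008904 was 8.41-fold lower in 7Su3rd and 6.95-fold lower in ACSu3rd, and CB_007732 was 5.63-fold and 9.63-fold lower. The files do not pair these identifiers with genes. The 12 probes that rose most in both lines, ranked by the smaller of the 2 changes, had a smaller change of 7.00-fold to 11.8-fold and held 8 CB, 1 XLOC, 1 H-InvDB, 1 UCSC and 1 RefSeq identifiers. The 12 that fell most had a smaller change of 4.68-fold to 6.95-fold and held 8 CB, 1 ENCODE, 1 H-InvDB, 1 UCSC and 1 RefSeq identifiers.

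**Figure D1:**
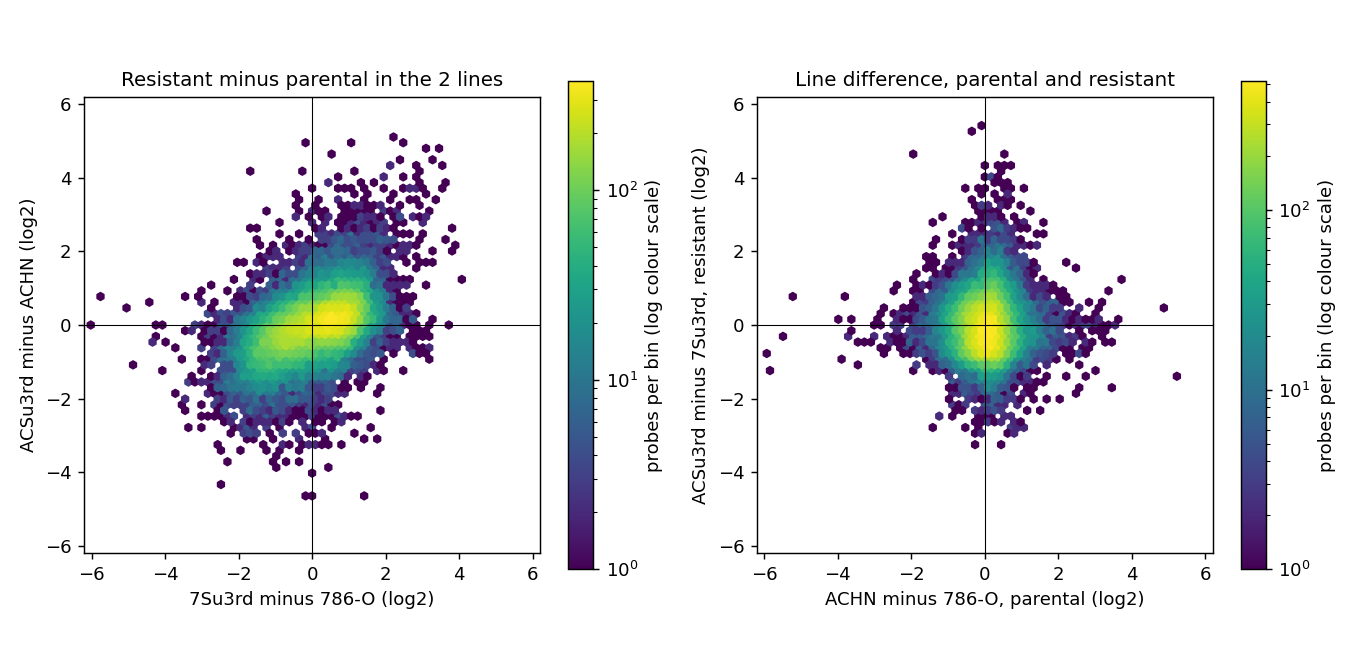
Each panel shows 35749 probes as hexagonal bins coloured by the number of probes on a log scale. The left panel sets the log2 difference 7Su3rd minus 786-O against ACSu3rd minus ACHN, which correlated at r = 0.48, and the right panel sets ACHN minus 786-O against ACSu3rd minus 7Su3rd, which correlated at r = 0.005.

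The differences of the 2 pairs correlated across probes with a Pearson's r of 0.48 and a Spearman's rho of 0.48, and 67.6% of the probes with a difference in both lines had the same sign. Without scaling r was also 0.48, but 49.1% had the same sign. With each derivative set against the parental array of the other line, r was 0.51 with the main scaling. The r of 0.48 is thus not particular to the pairing of each derivative with its own line. This follows from the correlation of 0.005 between ACHN minus 786-O and ACSu3rd minus 7Su3rd, so it is no separate evidence. Probes are not independent replicates, so no p-value is given. The 786-O pair had a standard deviation of 0.92 across probes and the ACHN pair 0.73, an order that turned with no filter, which gave 0.67 and 0.79. The parental arrays resembled each other more than either resembled its derivative: ACHN minus 786-O had a standard deviation of 0.53, and 1957 probes, 5.47%, differed at least 2-fold between them, against 28.9% in the 786-O pair and 13.6% in the ACHN pair. The 2 derivatives differed at least 2-fold at 10.8% of probes. ACSu3rd was closer to 786-O, with a standard deviation of 0.64 and 9.71% of probes changed, than to ACHN, with 0.73 and 13.6%. 7Su3rd was closer to 786-O, with 0.92 and 28.9%, than to ACHN, with 0.98 and 30.4%. Of 195 probes that differed at least 4-fold between the parental arrays, 99 differed with the same sign between the derivatives. Because of this likeness, the names 786-O and ACHN below stand for the arrays so labelled.

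Over both lines, limma gave 2447 probes at an adjusted p under 0.05, of which 960 were higher and 1487 lower in the resistant group. Of these, 1677 were at least 2-fold changed the same way in both lines and the other 770 were not. With 1 common standard error for all probes, a call depended only on the size of the mean log2 difference. The smallest size called was 1.26. The SD between the lines given below for a probe did not set that probe's p-value. Among the HOX-locus probes, 2 rose and 3 fell, and the same numbers passed when the adjustment was made over the list alone, a list chosen after the data were seen. nc-HOXD3-38 fell by 2.21 ± 1.04 on the log2 scale (SD, n = 2 lines) with a limma adjusted p of 4.6e-05, and nc-HOXD3-39 fell by 1.38 ± 0.29 with an adjusted p of 0.028, with the 7Su3rd differences of both taken at their bounds. The call of int-HOXB3-83, 1.67 ± 2.23 with an adjusted p of 0.0047, rested on ACSu3rd, since its difference in the 786-O pair was 0.10. That of hox-HOXC13-51, -1.26 ± 1.67 with an adjusted p of 0.0499, rested on 7Su3rd, with a difference of -0.08 in the ACHN pair. The fifth, nc-HOXC6-250, had a mean of 1.30 ± 1.19 and an adjusted p of 0.042, and it rested on 7Su3rd, where the difference was a bound of 2.14 against 0.46 in the ACHN pair. The count depended on the array and on the variance model: without 786-O it was 913 (383 higher and 530 lower), without ACHN 201 (128 and 73), without ACSu3rd 9873 (5253 and 4620), without the block by line 974 (349 and 625) and with quantile normalization 1577 (568 and 1009). More probes were also higher than lower without 7Su3rd, 900 against 855, and with the filter at the 75th percentile, 339 against 309. With no filter limma called 0 of 71497 probes, although 7355 had an unadjusted p under 0.05. The count depended on the scaling too, since limma called 157 probes without it, 45 higher and 112 lower.

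**Figure D2:**
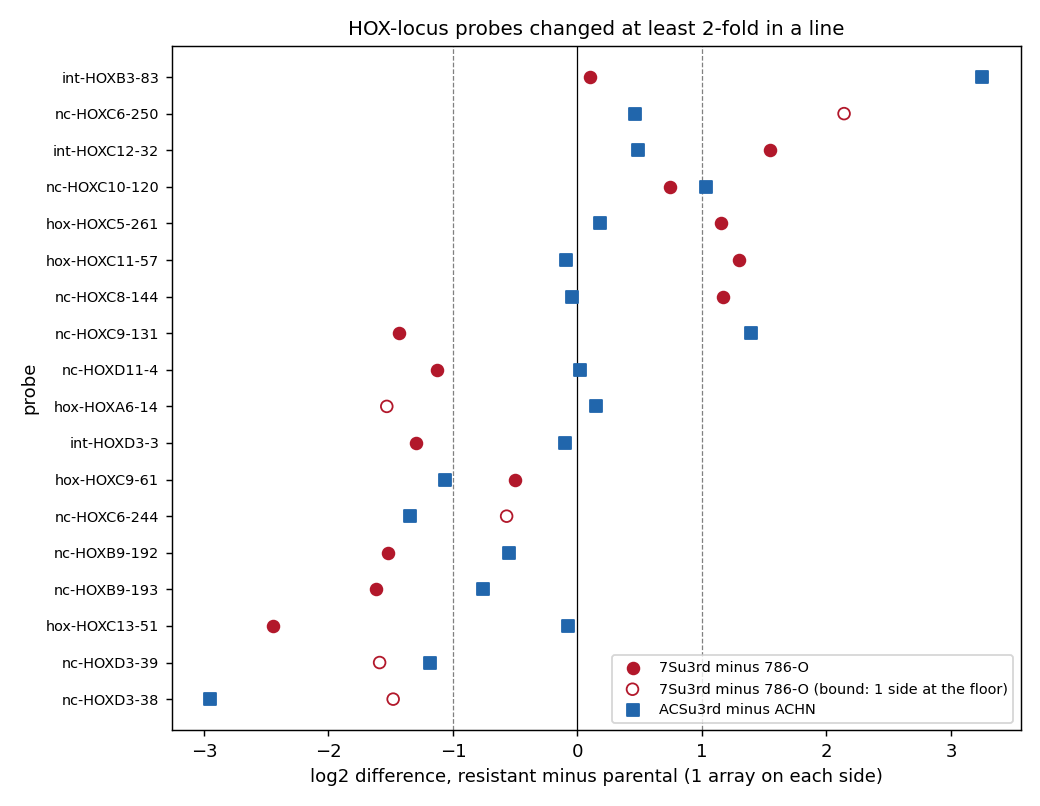
The horizontal axis gives the log2 difference of resistant minus parental for the HOX-locus probes that changed at least 2-fold in a line, with circles for the 786-O pair and squares for the ACHN pair, 1 array on each side. Open circles are bounds, dashed lines mark 2-fold, and nc-HOXD3-38 and nc-HOXD3-39 lie beyond the 2-fold line on the same side in both pairs.

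The 3 long intergenic non-coding RNAs that could be named and were kept did not pass the test. Their mean differences lay under 1.26, the smallest size called. TUSC8 was 1.49-fold higher in 7Su3rd and 1.47-fold higher in ACSu3rd, a mean log2 difference of 0.57 ± 0.01 (SD, n = 2 lines) with a limma adjusted p of 0.44. LINC01617 differed by 0.48 ± 0.24 with an adjusted p of 0.53, and LINC01233 by 0.06 ± 0.22 with an adjusted p of 0.95. In the 786-O pair, the differences of TUSC8 and LINC01617 were 0.58 and 0.65 with the main scaling and -0.43 and -0.36 with the intensities as deposited.

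Probes were grouped by the catalogue in their identifiers. The 17 snoRNA_scaRNA probes, for small nucleolar and small Cajal body RNAs that guide RNA modification, had a median difference of 1.37 in the 786-O pair, above all 10000 matched random lists, and 11 of them were at least 2-fold higher. In the ACHN pair their median was 0.16, at percentile 84.4, with 4 at least 2-fold higher. The 330 asoverlaps probes had medians of -0.36 and -0.14 in the 786-O and ACHN pairs, below all 10000 random lists in each, and the 113 UCRs probes had medians of -0.56 and -0.21. The 110 EvoFold probes, named after a predictor of conserved RNA structures, had medians of -0.57 and -0.14, and the 620 NRED probes had -0.15 and -0.08. These 5 classes passed camera at a preset correlation, with adjusted p values of 0.0047 for snoRNA_scaRNA, 0.0043 for asoverlaps, 0.0043 for UCRs, 0.015 for EvoFold and 0.025 for NRED. Without the 7Su3rd array none of the 5 passed, with adjusted p values of 0.054 for asoverlaps and EvoFold, 0.062 for UCRs, 0.12 for NRED and 0.19 for snoRNA_scaRNA. With no filter none of them passed camera, with adjusted p values of 0.13 for asoverlaps, UCRs and NRED, 0.30 for EvoFold and 0.54 for snoRNA_scaRNA. With an estimated correlation none of them passed, with an adjusted p of 0.83 for the 4 lower classes and 0.95 for snoRNA_scaRNA. The fry test, which sets each class against no change and not against other probes, gave adjusted p values of 0.56 and 0.77.

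The 1529 RNAz probes, another set of predicted structured RNAs, had medians of 0.36 and 0.20, above all 10000 random lists in both pairs, but limma called 30 of them higher and 53 lower over both lines, and their camera adjusted p was 0.12. It was 0.021 with quantile normalization, 0.013 without 7Su3rd, 0.017 without ACHN, 0.42 without 786-O and 0.51 without ACSu3rd, and the adjusted p was 0.83 with an estimated correlation for RNAz, XLOC and imsncRNA alike. The 1362 XLOC probes had medians of 0.25 and 0.12, also above all 10000 lists in both pairs, with an adjusted p of 0.25, which was 0.015 without 7Su3rd, 0.027 without ACHN, 0.85 without 786-O and 0.92 without ACSu3rd. The 413 imsncRNA probes had medians of 0.29 and 0.23 and an adjusted p of 0.42, which was 0.013 without 7Su3rd, 0.057 without ACHN, 0.85 without 786-O and 0.99 without ACSu3rd, and limma called 12 of them higher and 23 lower.

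**Figure D3:**
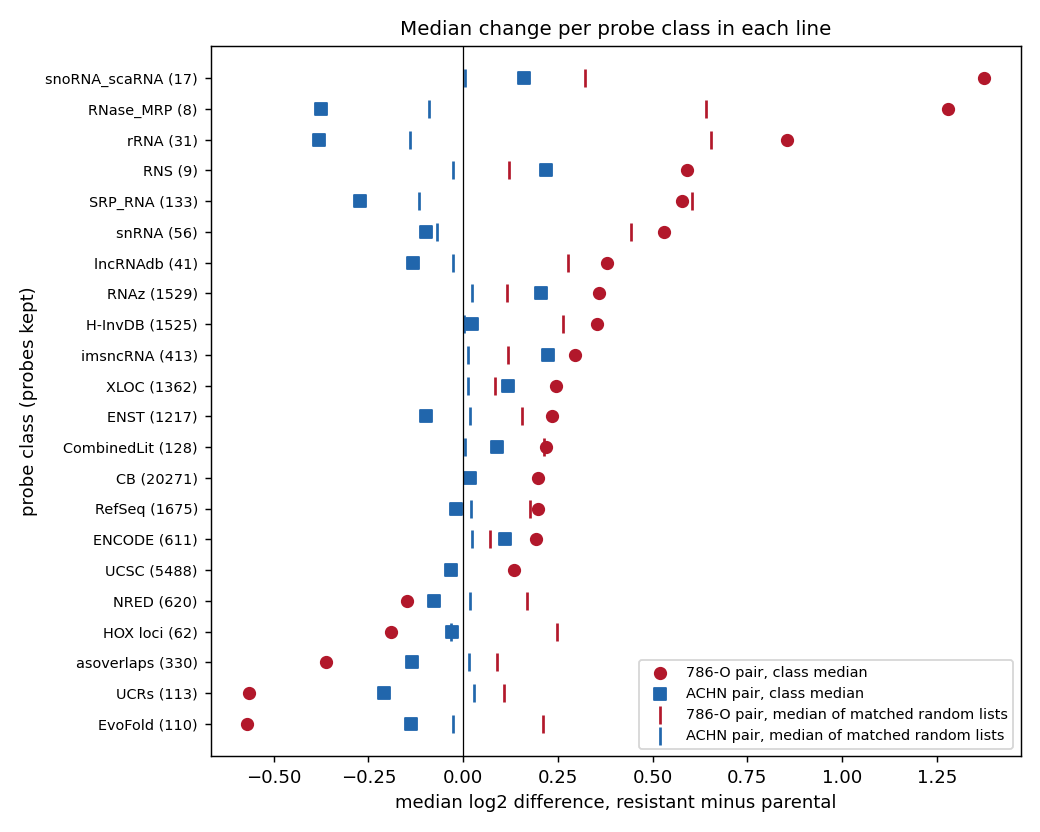
The horizontal axis gives the median log2 difference of resistant minus parental per probe class, as circles for the 786-O pair and squares for the ACHN pair, with the number of probes kept in parentheses. Short vertical lines mark the median of expression-matched random lists, drawn for all classes but CB and UCSC, and the snoRNA_scaRNA median of 1.37 in the 786-O pair is the highest shown.

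Control probes give the level of the arrays apart from the scaling. Human GAPDH, a glycolytic enzyme used as a reference, read 89961 in 786-O, 90043 in 7Su3rd, 84659 in ACHN and 87416 in ACSu3rd on the probe Human-GAPDH_3. After scaling this probe was 1.02 higher in 7Su3rd on the log2 scale and -0.12 in the ACHN pair. Human-PGK1_3, for another glycolytic enzyme, read between 26314 and 31564 on the 4 arrays. Because the derivatives passed through mice, the mouse probes were read too. Mouse-PGK1_3 was under the floor on all 4 arrays, and Mouse-GAPDH_5 was under it in 7Su3rd and between 27.9 and 33.3 on the other 3. Mouse-GAPDH_3 read 174 and 152 in the parental arrays and 112 and 167 in the resistant ones. Mouse-PGK1_5 was well above the floor on all 4 arrays, with 1954 and 1717 in the parental arrays, which hold no mouse-grown cells per the labels, and 1493 and 1518 in the resistant ones. The probes were not calibrated against mouse RNA here, so these levels give no mouse share.

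The E1A probes are Agilent's spike-in controls, meant for transcripts from outside the sample. The 8 with signal above the floor on all 4 arrays had scaled differences from -0.53 to 1.54 in the 786-O pair, a range of 2.07. The range was 0.58 in the ACHN pair and 0.49 between the parental arrays. The median scaled difference was 1.20 in the 786-O pair, -0.04 in the ACHN pair and 0.29 between the parental arrays. With the main scaling, the median spike-in difference in the 786-O pair was thus above the 2-fold threshold of 1 on the log2 scale. The cause of this level was not tested.

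**Figure D4:**
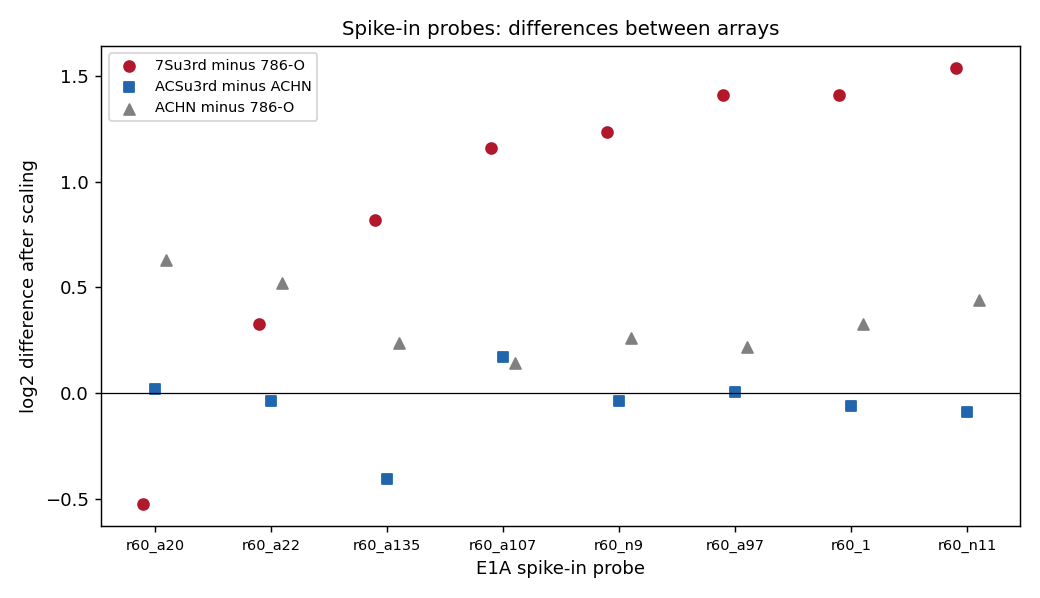
The vertical axis gives the log2 difference after scaling for each of the 8 E1A spike-in probes, with circles for 7Su3rd minus 786-O, squares for ACSu3rd minus ACHN and triangles for ACHN minus 786-O. The circles spread from -0.53 to 1.54, the squares from -0.41 to 0.17 and the triangles from 0.14 to 0.63.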

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

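The correlation of the 2 pairs' differences and its value after quantile normalization were planned, and the other tests of the patterns below were chosen after the results were seen.

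The probe nc-HOXC9-131 moved in opposite directions in the 2 lines. It was 2.71-fold lower in 7Su3rd than in 786-O and 2.62-fold higher in ACSu3rd than in ACHN, a gap of 2.83 on the log2 scale. The difference between the lines was not tested, since each has 1 array per state. The medians of 2 probe classes also lay on opposite sides in the 2 pairs, each outside the central 95% of matched random lists, and these differences were not tested either. For the ENST class the median was 0.23 in the 786-O pair and -0.10 in the ACHN pair, a gap of -0.33. For the 8 RNase_MRP probes it was 1.28 and -0.38, a gap of -1.66. Their matched random lists had medians of 0.64 and -0.09, so part of this gap was shared by probes of like intensity. Whether the 8 probes read separate transcripts is not given in the sources used here, so they may not be independent members. With quantile normalization the RNase_MRP medians were 0.67 and -0.23, with 2 in place of 8 probes at least 2-fold higher in 7Su3rd.

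Signal also appeared on control probes that no comparison used. Of 12 ERCC probes, for synthetic external RNAs, 2 were above the floor on all 4 arrays. ERCC-00012_90 read 278 in 786-O, 522 in 7Su3rd, 267 in ACHN and 402 in ACSu3rd, a mean scaled difference of 1.17 between resistant and parental arrays. ERCC-00043_129 had a mean scaled difference of 0.40, while its differences in the intensities as deposited were -0.25 in the 786-O pair and 0.20 in the ACHN pair.

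The first pattern weighed is the likeness of the parental arrays. Were line-specific expression kept by each derivative, ACHN minus 786-O and ACSu3rd minus 7Su3rd would run together across probes, but they correlated at r = 0.0047. The scaling and dim signal do not account for this, because r was 0.0039 after quantile normalization and -0.016 over probes above 8 times the negative control on all 4 arrays. That both parental arrays may hold RNA from 1 source cannot be told apart from lines that are truly alike on these probes: the standard deviation of ACHN minus 786-O was 0.53, and no repeat array of 1 RNA sets the technical spread. A wrong label on 1 array, and a change of line-specific expression during growth in mice or under the drug, stay open and were not tested.

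The second pattern is the correlation of the 2 pairs' differences. An intensity trend left by the scaling is argued against by the correlation of 0.49 after quantile normalization, and dim signal by the 0.44 over bright probes. That like parental arrays act as a shared control stays open. A response to sunitinib and the passage through mice, which both derivatives share, stay open and were not tested.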

How the results depend on the processing

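No scaling, no floor, the floor at 3 times the negative control, no filter with no floor, and the tests of probe classes were added after the data were seen. Every count stayed within 1.5 times the main one with median centring, log2(intensity + 16), no floor, the floor at 3 times and the filter on the highest array, as did the limma count with eBayes trend or robust. No cause was tested unless one is named.

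In the 786-O pair, the counts of higher and lower probes were 3039 and 1343 with the filter at the 75th percentile, where fewer probes are compared, 11961 and 8512 at 1.5-fold, 285 and 494 at 4-fold, and 313 and 15471 without scaling, and 29375 were higher with no filter and no floor. In the ACHN pair they were 7145 and 5171 with no filter, 703 and 703 with the filter at the 75th percentile, 5902 and 6199 at 1.5-fold, 381 and 336 at 4-fold, and 9334 and 6268 with no filter and no floor. In both pairs they were 339 and 263 with the filter at the 75th percentile, 3473 and 3507 at 1.5-fold and 81 and 52 at 4-fold, 147 were higher without scaling, and 6388 were higher with no filter and no floor. The correlation of the pairs was 0.34 with no filter and 0.29 with no filter and no floor.

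The limma count of 2447 was 974 with no replicate block, 648 with the filter at the 75th percentile, 1577 with quantile normalization, 157 without scaling, 0 with no filter and 0 with no filter and no floor. With no filter the prior degrees of freedom fell from infinite to 0.48, and 7355 probes had an unadjusted p under 0.05. Leaving out 1 array at a time, with no block and with the lone array assumed to vary like the other group, gave 201 (without ACHN) to 9873 (without ACSu3rd). The number of probe classes past camera's threshold, 5 in the main setting, was 0 with an estimated correlation and with no filter, 2 with the filter at the 75th percentile, and 2 to 11 without 1 array. Without 7Su3rd it was 3, none of them among the 5.

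Over 25 named probes and the 175 values under another scaling, offset or floor, 160 moved by less than 1 SD between the lines. Of the rest, 15 moved further, 8 of them with no scaling, and 0 called values changed sign. This SD is widest where the lines disagree, as for int-HOXB3-83 with 2.23, so it hardly lets such probes move. No filter with no floor also repeats the values of no floor for these probes, so the 160 are not independent checks. Without 1 line a mean becomes the value of the other line, which for hox-HOXC13-51 is -2.44 or -0.08. The 23 gene lists and the median over the probes of a gene were not run, since no probe was paired with a gene. Signal over background limits 7Su3rd most, where 53.0% of probes were above the floor.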

Other observations

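The tests of explanations in this part were chosen after the results were seen.

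The third pattern is that, among the probes kept by the filter, the 786-O pair differed at more probes, 10332 at least 2-fold, than the ACHN pair with 4845. The order turned with no filter, 10959 against 12316, where the floor of 7Su3rd holds many dim probes, and at 4-fold the counts were 779 and 717. A higher background on the 7Su3rd array is argued against as the whole cause, because over probes above 8 times the negative control the standard deviation of the 786-O differences was still 1.29 times that of the ACHN differences. A technical shift on the 7Su3rd array that differs between probes is a candidate explanation. The range of the E1A spike-in differences was 3.57 times as wide in the 786-O pair as in the ACHN pair. It was widened by E1A_r60_a20 at -0.53 and E1A_r60_a22 at 0.33, while the others lay from 0.82 to 1.54. Control probes named DCP_20 lay from -0.98 to 0.11 and DCP_22 from -0.30 to 0.58. DCP_1 probes above the floor lay from 0.81 to 1.31, so the shift followed groups of probes. A different amount of the spike-in mix would shift all these alike. A shift of the array's probes cannot be told apart here from a change in the spiked transcripts. A larger biological change in 7Su3rd was not tested and stays open.

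Across the 8 spike-in probes the differences of the 2 pairs correlated at r = -0.027, and the correlation over the 35749 sample probes was 0.48. The first value is imprecise, since it rests on 8 probes and E1A_r60_a20 and E1A_r60_a22 stand apart in the 786-O pair. Setting the 2 values side by side therefore does not test a technical cause of the shared pattern.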
